A study of Mus musculus with 24 samples.

How the data were processed

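The series holds 24 gene expression arrays. Of these, 22 arrays measured RNA from 11 cell lines grown out of lung tumours of mice carrying c-Myc and c-Raf transgenes, and 2 arrays measured alveolar type II cells isolated from healthy mice without the transgenes, the control. Per the labels' protocols, lungs were perfused, lavaged and digested with trypsin, type II and tumour cells were taken from a discontinuous Percoll gradient, the lines were passaged weekly in medium with calf serum for up to 50 passages, and RNA was labelled with biotin and hybridised to arrays. The array is an Affymetrix mouse design with 12488 probe sets.

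The deposited values are intensity signals per probe set on a linear scale, made with Affymetrix's GCOS software per the submitters' processing notes, which give no version. The mean signal after removing 2% of probe sets at each end was nearly equal on all arrays, so the deposited signals had been scaled array by array to one trimmed mean. Background correction, detection calls and any filter are not given in the sources used here. A common trimmed mean fixes the average level of every array, so a difference is read relative to the other RNAs of the same cells and not per cell. Each value is the only reading of its probe set on its array, and the number of arrays limits the precision: 5 lines have 3 arrays, 1 line has 2, 5 lines have 1, and the control has 2. The labels do not say whether repeat arrays came from separate cultures or the controls from separate animals, so p-values measure the spread between these samples, part of which may be technical.

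The 66 Affymetrix control probe sets were left out. Of the remaining 12422 probe sets, the platform annotation gave 1 gene symbol to 10833, several to 396 and none to 1193; a probe set with several symbols was tested but not named. Signals were transformed as log2(signal + 32), so that differences among very low signals are compressed and a log2 difference against a signal near the floor is smaller than the ratio of signals. A probe set was tested when its signal lay above its array's median on at least 2 arrays, which left 7670 and removed genes seen on only 1 control array. Where a gene is named, it stands for its brightest tested probe set, giving 5825 genes.

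Tumour lines were compared with control in limma 3.58.1 (R 4.3.3). Arrays of a line were averaged on the log2 scale, and the 11 line means were fitted against the 2 control arrays, with 11 residual degrees of freedom and moderated variances. The fit assumes the same spread for lines and controls and takes it mostly from the 11 lines. Where the 2 controls lie further apart than the lines, SE and p-values overstate the precision. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 and at least a 2-fold difference; all adjusted p-values for single genes are limma's. In another limma fit, 12 group means were fitted to all 24 arrays with 12 residual degrees of freedom; it gave each line's contrast with control and a moderated F-test over the 11 lines. Lines with 1 array are assumed there to vary like the others. Gene lists were tested with camera on the comparison of line means with control, at a preset correlation of 0.01 between genes, adjusted over the 21 lists with at least 3 tested members, and again with an estimated correlation. For each of the lists the count of calls adjusted over the list alone equalled the count over all probe sets.

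The design, the 23 lists, the rule for naming genes and most alternatives were fixed before the data were examined. The rule took the 10 largest rises and the 10 largest falls among called genes with every line on the same side of both control arrays, up to 2 called members with the largest change per list (or the largest change where none was called), Myc, and the 10 genes with the largest spread of line means among those past the F-test. Genes named outside the rule are Marco, Slc34a2, Hc, Chil1, Vim, H2-Aa, Cd79b, Upk3b, Msln, Wt1, Peg3 and Sgce.

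Alternatives were quantile normalization, centring each array on its median, offsets of 1 and 100, a floor of 32, no filter and a stricter filter, other variance models, 1 array per line, the line as a random block over all arrays, other fold thresholds, leaving out each line, control or array, the replicate number as a block, and for lists an estimated correlation, fry and averaging of a gene's probe sets. Both fits were tested on simulated data with the 7670 probe sets' own means and spreads, of which 200 were changed. The simulated noise was independent between probe sets and arrays and equally wide in lines and controls. It held no difference between unnumbered and numbered arrays, so the shares and false calls below may be too favourable for the real data. For the 11 lines against 2 control arrays, 98% of 4-fold and 44% of 2-fold changes were called, with 2 calls among 7470 unchanged probe sets. For the test among lines, with 1 line of 3 arrays changed, 86% of 4-fold and 34% of 2-fold changes were called, with 4 calls among the unchanged.

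The title of line 9 names it gammaB8, which is used here, while another label of the same arrays reads gammaA8. Repeat arrays are named unnumbered, replicate 1 and replicate 2, after their labels.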

Results

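The arrays compared 11 cell lines, grown out of lung tumours of mice with c-Myc and c-Raf transgenes, with alveolar type II cells, the surfactant-producing cells of the lung lining, from healthy mice. c-Myc is a transcription factor that drives growth and division, and c-Raf is a kinase upstream of MEK and ERK. Median signals were 53.2 to 75.5 on the 22 tumour arrays and 93.8 and 108 on control arrays 1 and 2. The ratio of the 3' to the 5' actin probe sets was 1.03 to 1.32 on tumour arrays and 1.47 and 1.64 on the control arrays. The control arrays were unlike each other: 952 of 7670 tested probe sets lay at least 2-fold apart between them, and their Spearman correlation was 0.913. Surfactant protein C (Sftpc) gave a signal of 787 on control 1 and 11196 on control 2, and the macrophage receptor Marco gave 1626 and 79.4. The type II markers Slc34a2, Hc and Chil1, not tested, gave 58.5, 19.8 and 51.2 on control 1. On control 2 they gave 5029, 1173 and 1245. The 6 tested type II markers had median log2 levels of 9.00 and 11.79 on controls 1 and 2 and 6.02 in the lines.

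The tumour lines were compared with the control cells to find how the cultured lines differ from freshly isolated alveolar cells. The lines had been passaged in medium with serum and the control cells had not. Effects of transformation and of culture therefore cannot be told apart in any difference below. In the lines, most measured cell cycle, Myc target and mesenchymal transition genes rose, and most markers of epithelial junctions, type II cells and myeloid cells fell. As whole lists, only the epithelial and myeloid genes passed with an estimated correlation (adjusted p = 0.00399 and 0.0275), against 0.284 for cell cycle and for Myc target genes and 0.125 for mesenchymal genes. Among the 10 largest rises was the neurotrophin Bdnf, from signals of 110.4 and 41.4 on the control arrays to 2602 ± 833 (SD, n = 11 lines), a log2 difference of 4.58 (SE 0.37). The chromatin protein Hmga2 rose to 1742 ± 796 from 80.9 and 4.40 (log2 difference 4.56, SE 0.56), and N-cadherin (Cdh2) rose to 1294 ± 257 from 59.6 and 6.40 (4.44, SE 0.28). The order among these depended on the offset and the control kept, and the other log2 rises were in the collagen cross-linking enzyme Lox (4.41), Cyp1b1 (4.31), the mitotic kinesin Kif20a (4.18), the mitotic kinase Cdk1 (4.11), the chemokine Cxcl12 (4.10), the matricellular protein Ccn4 (3.81) and the ribonucleotide reductase subunit Rrm1 (3.80). Their adjusted p lay between 3.1e-09 and 2.3e-05, with all 11 lines above both control arrays. Without control 2 the log2 difference of Lox was 2.72.

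The 10 largest falls took in genes of secretory cells and macrophages, among others. The club cell secretoglobin Scgb1a1 went from 5729 and 10348 on the control arrays to 15.6 ± 9.42 in the lines (log2 difference -7.39, SE 0.23). Lysozyme 2 (Lyz2), listed here with the myeloid markers, went from 6099 and 5582 to 5.04 ± 4.33 (-7.33, SE 0.14). Which cells of the control preparations held its RNA was not tested. The other log2 differences were -7.36 for the macrophage lectin Chil3, -7.13 for cathepsin S (Ctss), -6.39 for Mpeg1, -6.35 for Plet1, -6.24 for Wfdc2, -6.18 for apolipoprotein E (Apoe), -6.12 for Chchd10 and -6.03 for the myeloid adaptor Tyrobp. Their adjusted p lay between 3.1e-15 and 2.6e-10, with all 11 lines below both control arrays. In all, 1265 probe sets (974 genes) were higher and 1638 (1241 genes) lower in the lines at an adjusted p under 0.05 and at least 2-fold. Every line lay above both controls for 1949 probe sets and below both for 2275, together 55.1% of those tested, where chance ordering of 13 values gives 2.56%. The split of calls rested on scaling: 1671 higher and 1370 lower after quantile normalization, and 2421 higher and 923 lower after centring arrays on their medians. With a stricter filter 1240 were higher and 900 lower. The median log2 difference over all tested probe sets was -0.05 as deposited, 0.18 after quantile normalization and 0.49 after centring.

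Proliferation genes rose together. Of 23 measured cell cycle genes, 21 rose and none fell, with a median log2 difference of 2.42 (camera adjusted p = 5.4e-09; adjusted p = 0.284 with an estimated correlation). On A2B1 replicate 1 the medians of these and of the Myc target genes below, 7.95 and 8.54, lay under those of control 1, 8.01 and 8.76. Cdk1 rose to 3780 ± 727 from 270.0 and 115, and the mitotic kinase Aurka rose to 807 ± 221 from 80.5 and 29.7 (3.24, SE 0.34). Of 21 measured Myc targets, chiefly nucleolar and ribosome assembly genes, 17 rose and none fell, with a median of 1.72 (adjusted p = 2.9e-07; adjusted p = 0.284 with an estimated correlation). The nucleolar protein Nop56 rose by 2.98 (SE 0.32) and nucleophosmin (Npm1) by 2.51 (SE 0.16), the latter to 10857 ± 877 from 2378 and 1468. Myc itself had a signal of 338 ± 77.9 in the lines and of 283 and 79.8 on control arrays 1 and 2. Whether this probe set also reads the transgene is not given in the sources used here, so the value may not measure total Myc RNA. Its log2 difference of 0.92 (SE 0.32, adjusted p = 0.0195) lay under the 2-fold threshold, with 8 of 11 lines above both controls, and was 0.18 without control 2. It passed both thresholds without control 1 (1.67), without A2B1 replicate 1 (1.00), after quantile normalization (1.28) or centring (1.46), with an offset of 1 (1.09) and with a floor of 32 (1.10).

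Epithelial and mesenchymal genes moved apart. All 14 measured genes for epithelial junctions and keratins fell, with a median log2 difference of -3.59 (camera adjusted p = 2.1e-08; adjusted p = 0.00399 with an estimated correlation). Keratin 18 (Krt18) fell from 2048 and 824 to 17.2 ± 6.83 (-4.78, SE 0.24) and keratin 8 (Krt8) from 3646 and 1467 to 56.5 ± 15.3 (-4.78, SE 0.26). Of 10 measured mesenchymal transition genes, 8 rose and 1 fell, with a median of 1.77 (adjusted p = 0.00528; adjusted p = 0.125 with an estimated correlation). Cdh2 led the rises, while Tgfbi, a matrix protein induced by TGF-beta, fell (-2.64, SE 0.37; -1.73 without control 2). Vimentin (Vim) was not tested, since its probe set gave only 51.1 and 20.8 on the control arrays and 21.8 in the lines. Fibroblast markers went both ways: 3 of 12 rose and 4 fell, with a median of -0.30, a mean of 0.00 and an adjusted p of 0.975. Collagens Col1a1 (3.77, SE 0.45; 2.48 without control 2) and Col1a2 (3.19, SE 0.66) rose, though another Col1a2 probe set was called lower.

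Markers of type II, myeloid, lymphoid and club cells were mostly lower in the lines, while type I, fibroblast and mesothelial markers as lists were not called. A marker silent in the lines was tested only where both control arrays held it, so the share of tested members that fell is partly set by the filter. Without the filter 10 of 11 type II markers, 17 of 17 myeloid, 9 of 13 lymphocyte and 9 of 11 endothelial markers fell, and these lists stayed called. All 6 tested type II markers fell, with a median log2 difference of -4.74 (camera adjusted p = 0.000975; adjusted p = 0.284 with an estimated correlation). Sftpc fell by 5.81 (SE 0.57) and the protease Napsa by 5.07 (SE 0.50, and -3.29 without control 2). These SE rest mostly on the spread among lines. Controls 1 and 2 stood at log2 levels of 9.68 and 13.45 for Sftpc and of 8.43 and 11.99 for Napsa. All 16 tested myeloid markers fell, with a median of -4.45 (adjusted p = 7.2e-12; adjusted p = 0.0275 with an estimated correlation), and the control arrays held them at median log2 levels of 11.03 and 10.34 against 5.51 in the lines. All 6 tested lymphocyte markers fell (median -2.48, adjusted p = 0.000417; adjusted p = 0.284 with an estimated correlation), among them Cd52 (-4.68, SE 0.21) and Coro1a (-4.35, SE 0.18). Of 4 club cell markers 3 fell (median -3.47, adjusted p = 0.0146; adjusted p = 0.284 with an estimated correlation), including Cyp2f2 (-5.22, SE 0.55; -3.35 without control 2). Of 5 endothelial markers 4 fell and 1 rose (median -2.95, adjusted p = 0.0374; adjusted p = 0.350 with an estimated correlation), with von Willebrand factor (Vwf) at -3.72 (SE 0.20) and Cldn5 at -2.98 (SE 0.31; -1.93 without control 2). The endothelial call was lost without line A2C12 (median -2.96) or with an offset of 100 (-1.81), and without control 2 the median was -1.93. Of 6 type I cell markers 3 fell and 1 rose (median -0.54, adjusted p = 0.379), with Ager at -3.93 (SE 0.32) and Hopx at -3.59 (SE 0.27). The ciliated markers Foxj1 (-3.17, SE 0.29) and Rsph1 (-1.74, SE 0.19), too few for a list test, fell, and no erythroid marker passed the filter.

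**Figure D1:**
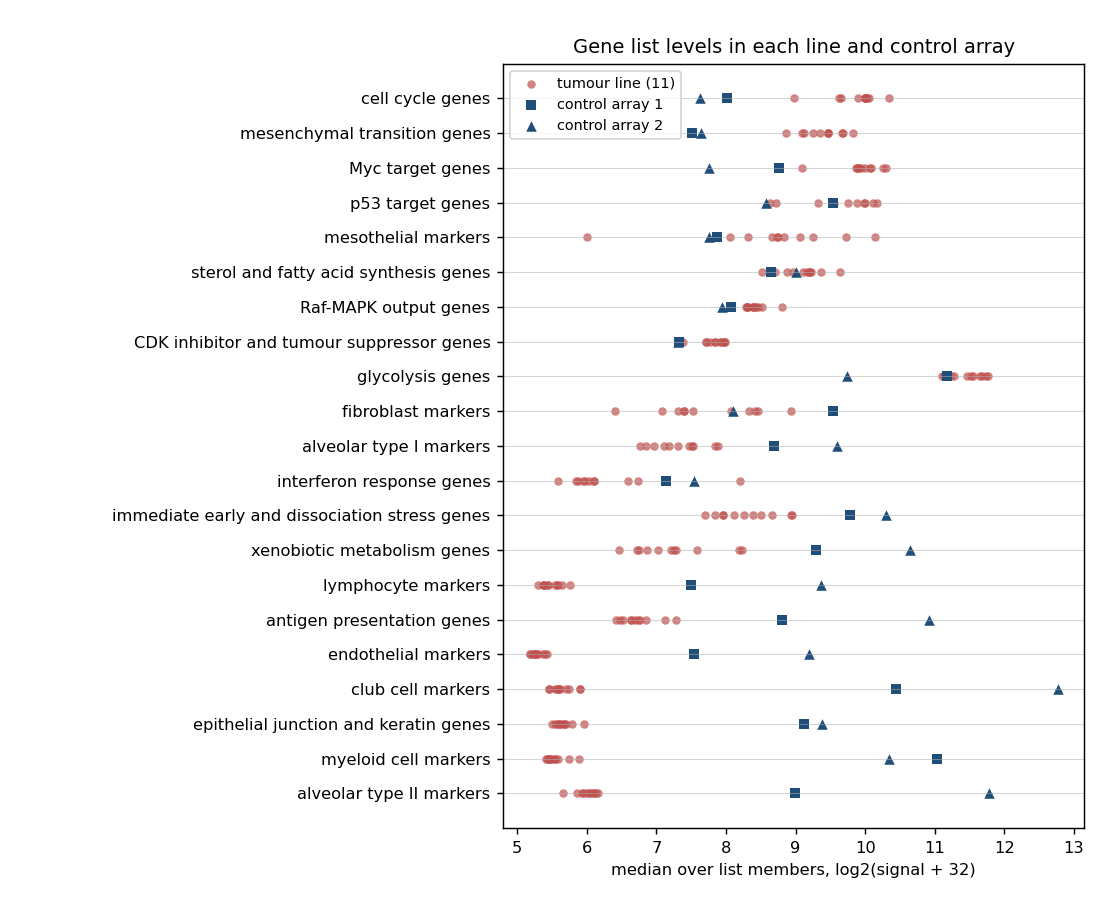
Median level of each gene list, as log2(signal + 32) on the horizontal axis, for the 11 tumour lines (red circles, each the mean of a line's arrays) and the 2 control arrays (blue square and triangle). The cell cycle medians of the lines lay between 8.98 (A2B1, arrays at 9.81 and 7.95) and 10.34, above both controls, and the myeloid medians between 5.41 and 5.88, below both.

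Most antigen presentation genes and most immediate early genes fell. Of 12 measured antigen presentation genes 10 fell (median log2 difference -2.91, camera adjusted p = 0.00123; adjusted p = 0.298 with an estimated correlation), and without control 2 the median was -1.77. The invariant chain Cd74 stood at -4.20 (SE 0.65), -6.44 without control 1 and -1.95 without control 2, and the class I gene H2-K1 at -3.84 (SE 0.58). The class II gene H2-Aa, not tested, gave 11.5 on control 1 and 4889 on control 2, and the B cell gene Cd79b 12.2 and 532, so immune cells in the control preparations are not set apart from a loss in the epithelium. Of 18 immediate early and dissociation stress genes 10 fell and 2 rose (median -1.64, adjusted p = 0.0103; adjusted p = 0.371 with an estimated correlation), with Fos at -4.03 (SE 0.67) and the mRNA decay factor Zfp36 at -3.82 (SE 0.31). This call was lost without control 2 (median -0.99). The control cells came from lungs digested with trypsin, so a response to isolation cannot be told apart from a lower level in the lines. Within lines, Fos was also higher on unnumbered than on numbered arrays, by 1.65 in log2. Of 14 xenobiotic metabolism genes 8 fell and 1, Cyp1b1, rose (median -2.32, adjusted p = 0.0912). The cytochromes Cyp2b10 (-4.93, SE 0.26) and Cyp4b1 (-4.59, SE 0.39) fell furthest, and the list passed the threshold without control 1 (-2.99), after quantile normalization (-2.63) or after centring (-1.79). Of 12 interferon response genes 5 fell and 1 rose (median -0.84, adjusted p = 0.285), with Usp18 at -2.67 (SE 0.52) and Ifit2 at 2.10 (SE 0.36); without line A2B1 the list was called (median -0.93).

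Lists for signalling and metabolism did not pass camera. Of 12 Raf-MAPK output genes 5 rose and 1 fell (median log2 difference 0.50, adjusted p = 0.322): Fosl1 rose by 2.30 (SE 0.46), a call lost without control 2 (1.19), and Egr1 fell by 1.95 (SE 0.29). Of 9 p53 targets 3 rose and 3 fell (median 0.82, mean 0.06, adjusted p = 0.466), with Plk2 at 1.97 (SE 0.38; 0.99 and not called without control 2) and Perp at -2.99 (SE 0.73). Of 10 cyclin-dependent kinase inhibitor and tumour suppressor genes 1 rose, Rassf1 (1.29, SE 0.25), and 1 fell, Rb1 (-1.08, SE 0.23; median of the list 0.44, adjusted p = 0.285). Rb1 was not called without control 1 (-0.85), after quantile normalization (-0.66), after centring (-0.55), with an offset of 100 (-0.70) or with 1 array per line (-0.97). Rassf1 was not called with an offset of 100 (0.96) or on numbered arrays only (0.95). Of 17 sterol and fatty acid synthesis genes 4 rose and 2 fell (median 0.55, adjusted p = 0.285), with the elongase Elovl6 at 1.85 (SE 0.35) and the desaturase Scd1 at -1.77 (SE 0.39; -0.95 and not called without control 2). Of 11 glycolysis genes 5 rose and none fell (median 0.43, adjusted p = 0.302), among them hexokinase 1 (Hk1, to a signal of 7219 from 3698 and 1638) and pyruvate kinase (Pkm, 1.40, SE 0.24). Neither was called without control 2 (log2 differences of 0.92 and 0.74), nor Pkm after quantile normalization (0.95), and without control 1 the list was called, at a median of 1.06. None of the 4 mesothelial markers was called; their median was 0.81 (adjusted p = 0.478), and Bnc1 stood at 1.30 (SE 0.71, adjusted p = 0.119), and was called without line A2C12 (1.60), after quantile normalization (1.74) and after centring (1.83).

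Each line was also set against the control cells by itself. In A2B1 1040 probe sets were higher and 1356 lower, 2396 in all, but 2832 without its replicate 1 array and 1925 without its unnumbered array. A2C12 had 1391 higher and 1725 lower, B3 had 1332 higher and 1719 lower, betaD5 1286 and 1673, betaD10 1208 and 1461, cRAF_cMYC 1298 and 1624, and gammaA3 1273 and 1662. In gammaA7 1278 were higher and 1602 lower, in gammaB8 1298 and 1585, in gammaD1 1240 and 1652, and in gammaD12 1193 and 1448. Cell cycle genes had a median log2 level of 8.98 in A2B1 and of 9.63 to 10.34 in the other 10 lines. Within A2B1 that median was 9.81 on the unnumbered array and 7.95 on replicate 1, which also had a Myc signal of 85.8 against 361 on the unnumbered array; the 2 arrays were at least 2-fold apart for 983 probe sets. All 11 contrasts share the same 2 control arrays, so their counts are not independent of each other and whether they differ was not tested.

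The lines were then compared with each other. The F-test called 262 of 7670 probe sets over all 11 lines (3.42%; 216 genes), 794 over the 6 lines with 2 or 3 arrays and 1584 over the numbered arrays of 5 lines. In the 1584 count only the spread between replicates 1 and 2 of a line sets the error. After centring each probe set these correlated at 0.892 in A2C12, 0.815 in B3 and 0.684 in gammaB8, but not in cRAF_cMYC and gammaA7. The unnumbered arrays of B3 and gammaB8 correlated with their numbered arrays at only -0.191 to 0.106. Whether that count reflects the line alone was not tested. Line A2C12 had the lowest or highest mean for 166 of the 216 genes. The retinal dehydrogenase Aldh1a1 gave a signal of 38.6 in A2C12 and of 1852 to 12345 in the other 10 lines, with 3779 and 7123 on the control arrays (F-test adjusted p = 0.000994); the single arrays of A2C12 gave 20.3, 94.2 and 1.27. The NADPH oxidase subunit Cyba gave 33.8 in A2C12 and 618 to 2836 elsewhere (adjusted p = 2.0e-07), and Plac8 gave 379 in A2C12 and 3605 to 12553 elsewhere (adjusted p = 0.000383). The basement membrane protein Nid2 was near the floor in A2C12 (0.646, a log2 level of 5.03) and highest in gammaD1 (a log2 level of 9.11), and the proteoglycan Dcn ran from 236 in A2C12, whose arrays gave 658, 32.4 and 17.5, to 5374 in A2B1. The chloride channel regulator Clca3a1 was highest in A2C12 (866) and in gammaA7 (620), whose arrays gave 1109.8, 670.4 and 80.2. The collagenase Mmp13 ran from 14.7 in betaD10 to 1086 in gammaD12, and Ndn, an imprinted gene, from 8.19 in gammaA3 to 470.3 in gammaA7. The metallothioneins Mt1 and Mt2, which bind zinc and copper, ran from 41.5 and 99.7 in betaD5 to 2307 and 2190 in gammaA7.

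Against control, Mt1 (-3.10, SE 1.07), Mt2 (-3.19, SE 0.90) and Plac8 (3.20, SE 0.93) were called over all lines. Without control 1 none of these calls held (Mt1 -2.61, Mt2 -2.37, Plac8 2.08), and Mt1 was not called without control 2 either (-3.59). On numbered arrays only, Mt1 (-1.40) and Plac8 (2.42) were not called, and with array weights Mt1 (-2.77) and Mt2 (-2.86) were not. Aldh1a1 (-0.48, SE 1.34), Dcn (-0.07, SE 1.13), Clca3a1 (1.05, SE 0.95) and Ndn (-0.47, SE 0.92) were not called. Nid2 (1.84, SE 0.97), Cyba (-1.74, SE 0.95) and Mmp13 (2.05, SE 0.92) were not called either, but were without line A2C12 (2.10, -1.33 and 2.26). Mmp13 was also called without betaD10 (2.33), with a floor of 32 (2.62), after quantile normalization (2.47) and after centring (2.59), Cyba after quantile normalization (-2.18) and Nid2 after centring (2.38).

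Interferon response genes also varied: 7 of the 12 measured passed the F-test, and the list's median log2 level was 8.21 in A2B1 and between 5.59 and 6.73 in the other 10 lines. The A2B1 arrays, at 7.75 and 8.57, lay above all other tumour arrays, of which the unnumbered gammaB8 array was highest (7.39; 6.35 and 5.94 on its replicates 1 and 2). Usp18 stood at a signal of 192 in its highest line, A2B1, and Ifit2 at 277. The mesothelial marker Bnc1 differed as well (adjusted p = 0.00589), with 16.2 in A2C12 and 263 to 927 elsewhere. No member of the epithelial, cell cycle, Myc target, type II or myeloid lists passed the F-test. The epithelial, type II and myeloid lists lay near the floor in the lines, at median log2 levels of 5.59, 6.02 and 5.51. The offset compresses differences there, so for these lists the result says little about likeness of the lines.

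**Figure D2:**
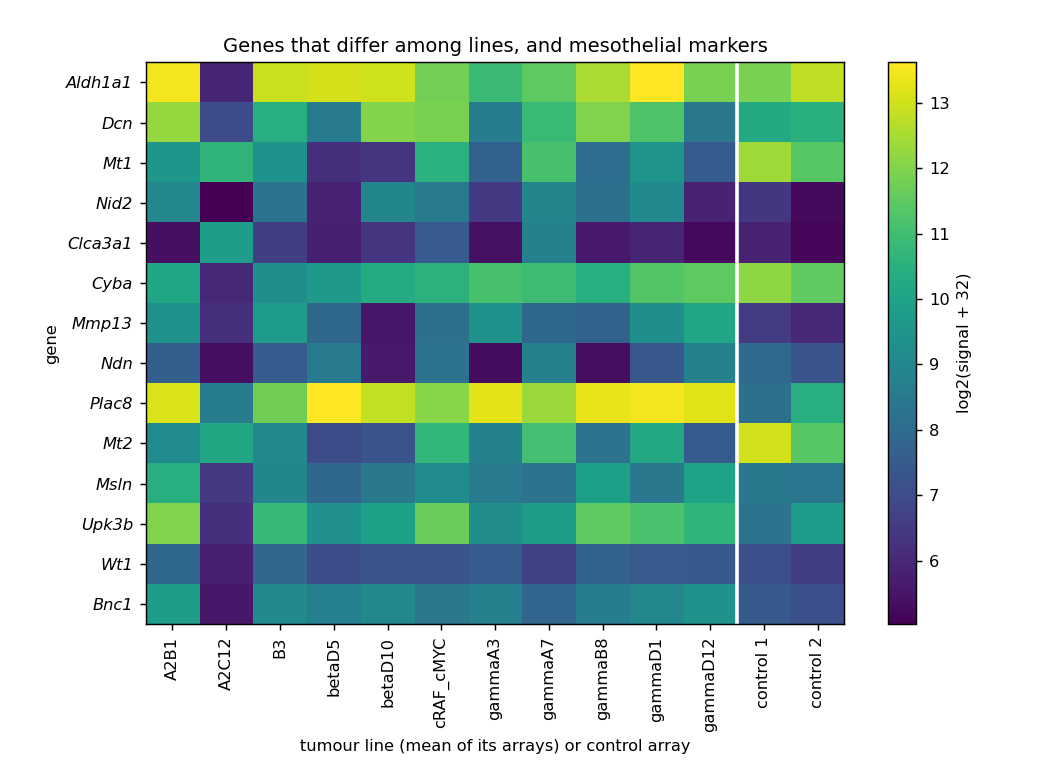
Log2(signal + 32) as colour for the 10 named genes that differ among lines and for the 4 measured mesothelial markers, in the 11 tumour lines (mean of each line's arrays) and the 2 control arrays to the right of the white line. The column of A2C12 is dark for Aldh1a1 (5.92), Nid2 (5.03), Cyba (6.03) and the mesothelial markers, and bright for Clca3a1 (9.80).

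In the F-test 1645 probe sets had an unadjusted p under 0.05. The median spread between arrays of a group was 0.29 (SD of log2 values), and that of line means was 0.26. Of the 17 arrays of lines with 2 or 3 arrays, 9 correlated best with an array of their own line. Over the 6 lines with both kinds, 1021 probe sets differed between unnumbered and numbered arrays within lines, of which 31 were at least 2-fold higher and 20 lower on the unnumbered arrays. With the replicate number as a block the F-test called 317 probe sets; the unnumbered arrays alone hold 1 per line and give no test. Replicate 1 of cRAF_cMYC correlated at 0.73 with replicate 1 of gammaA7 after centring each probe set, and replicate 2 of cRAF_cMYC at 0.83 with replicate 2 of gammaA7, against -0.03 and -0.01 within each of these lines. The count depended on single arrays: it was 788 without the unnumbered A2B1 array, 411 without the unnumbered gammaB8 array, 146, 93 and 83 without the unnumbered, replicate 1 and replicate 2 arrays of A2C12, 155 and 157 without replicates 1 and 2 of B3, and 163 and 164 without those of gammaB8.

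**Figure D3:**
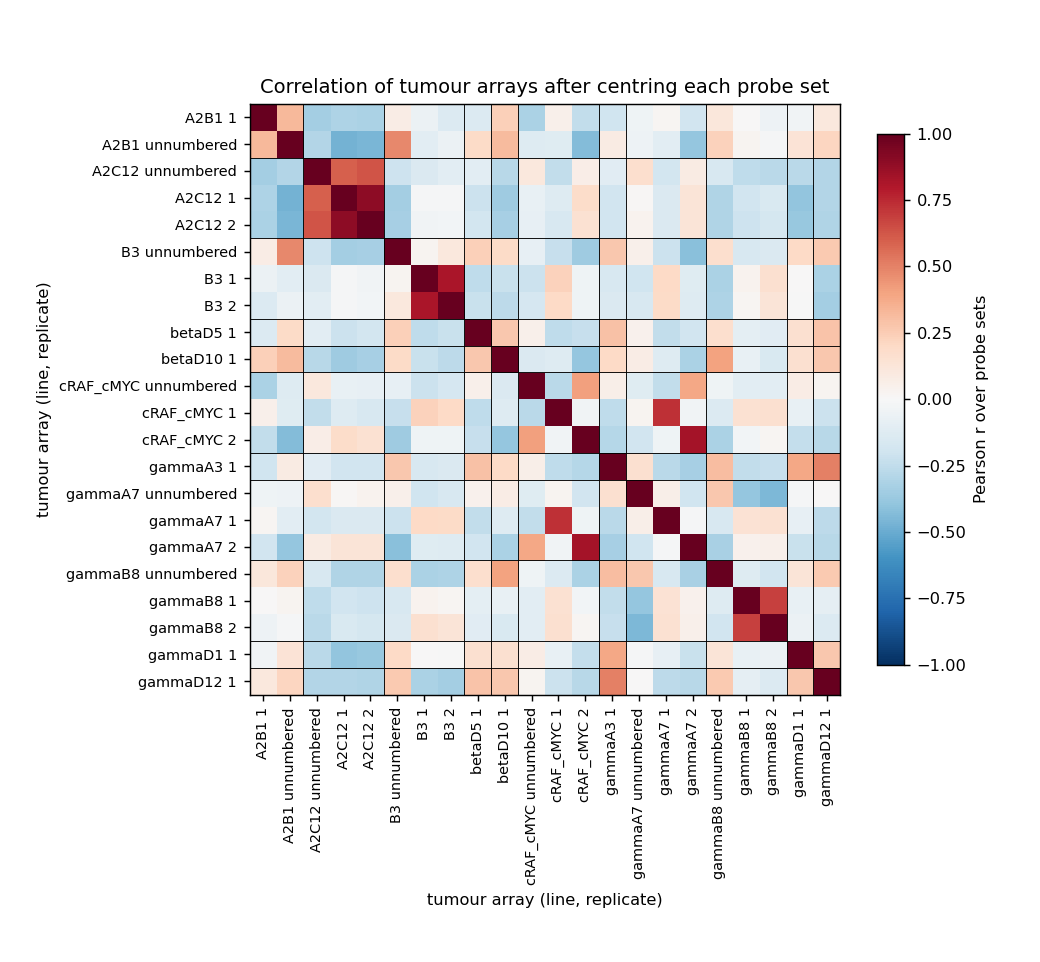
Pearson correlation over the 7670 tested probe sets between the 22 tumour arrays after subtracting each probe set's mean, as colour from -1 to 1, with black lines between cell lines. The 3 arrays of A2C12 form a block with correlations of at least 0.60, while cRAF_cMYC and gammaA7 show high values across the lines (0.73 and 0.83) and values near 0 between their own numbered arrays.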

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

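The tests of splits within arrays with and without a replicate number, of exchanged arrays, shared handling, other-cell RNA for myeloid and epithelial genes, and cross-hybridisation were chosen after the result was seen; the other splits, the scaling test and the test of further mesothelial genes were chosen before.

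The 10 genes with the widest spread among lines past the F-test stood out because lines of the same tumour model differed in them. The spread between the highest and the lowest line, in log2, was 7.68 for Aldh1a1. It was 5.24 for Dcn. It was 4.93 for Mt1, where the line is partly confounded with the kind of array, and 4.01 for Mt2. It was 4.08 for Nid2. It was 4.59 for Clca3a1. It was 5.46 for Cyba. It was 4.58 for Mmp13. It was 3.49 for Ndn. It was 4.95 for Plac8.

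The counts were set against splits of the same samples made without regard to their labels. Of 100 splits of the tumour arrays into groups of the same sizes, only the real 1 reached 262 probe sets, and the highest other gave 167. Those splits mixed arrays with and without a replicate number, kinds that differ within lines; of 100 splits that moved arrays only within each kind, again only the real 1 reached 262, and the highest other gave 67. Of the 78 ways to pick 2 of the 13 line means and control arrays, only the real 1 reached 1265 higher probe sets, where the highest other gave 11, and only the real 1 reached 1638 lower probe sets, where the highest other gave 9.

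Arrays of cRAF_cMYC and gammaA7 paired across the lines. The unnumbered cRAF_cMYC array correlated at 0.386 with gammaA7 replicate 2, at 0.410 with the matching cRAF_cMYC replicate 2 and at -0.268 with its own replicate 1. The unnumbered gammaA7 array correlated at 0.0562 and -0.203 with its own replicates 1 and 2, and at 0.0240 and -0.193 with those of cRAF_cMYC. An exchange of arrays would give such values for the unnumbered cRAF_cMYC array, but that of gammaA7 matched neither line. This mismatch does not weigh against an exchange. Unnumbered arrays of B3 (0.029 and 0.106) and gammaB8 (-0.125 and -0.191) did not match their own replicates 1 and 2 either, while that of A2C12 did (0.600 and 0.631). The test could not have gone against an exchange, so an exchange stays open. Handling common to all arrays of a number should raise such correlations in other lines as well, and among replicates 1 and 2 of A2C12, B3 and gammaB8 the highest was 0.130, which argues against it as the whole cause. Handling shared by cRAF_cMYC and gammaA7 alone was not tested, and arrays without a number did correlate across some lines (0.479 for A2B1 with B3, 0.502 for gammaA3 with gammaD12).

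Myeloid and club cell markers were far lower in the lines. On both control arrays 62.5% of the myeloid markers lay among the top 10% of all probe sets. A high control level follows from a large fall to near the floor, so this test could hardly have come out otherwise. RNA of macrophages in the control preparations therefore stays open as an explanation. RNA of airway cells stays open too, and no club cell marker entered the test. Scaling to one trimmed mean was argued against, since the myeloid median was -4.63 after quantile normalization. For epithelial genes the median percentile rank was 30.6 in the lines (SD 2.97 over lines) against 84.4 and 87.1 on the control arrays. The lines themselves thus held little of these RNAs, which RNA of other cells in the controls cannot produce. Set against the controls, the ranks restate the fall and do not tell type II cells from other epithelial cells as the source. How far the fall is one from type II cells therefore stays open.

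None of the 4 mesothelial markers was called against control, but some were high in most lines: Upk3b had signals of 585 to 5022 in 10 lines and 42.8 in A2C12 against 282 and 818 on the controls, and Msln 204 to 1389 and 60.4, but on the unnumbered gammaA7 array they gave 61.1 and 3.68. Msln in betaD5 (204) lay below both controls (333 and 304), and Wt1 gave 87.2 to 214 in the same 10 lines against 108 and 65.8 on the controls. Cross-hybridisation of single probe sets stays open: the means of all 4 markers were lowest in A2C12, but that line was lowest for 90 of the 216 genes that differed. A broader mesothelial programme stays open too: 6 further mesothelial genes had a median rank at percentile 2.59 of random lists, but ranks of different probe sets depend on their affinity, and only 2 of the 6 lay in the upper 50% on a control array.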

How the results depend on the processing

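The settings with numbered arrays only, without A2B1 replicate 1, and without cRAF_cMYC and gammaA7 were chosen after the result was seen; the other tests were set before. Against control there were 2 arrays, unlike each other, and their handling in relation to the tumour arrays is not given in the sources used here. Of 69 named genes, 54 stayed on the same side of the thresholds under every alternative, and 51 of these also kept their sign. Aldh1a1 (-1.22 to 0.11), Dcn (-0.29 to 0.47) and Ndn (-1.06 to 0.07), not called in any setting, did not keep it. No called result turned to the opposite direction. Centring arrays on their medians gave 2421 higher and 923 lower probe sets, which follows from the lower medians of the tumour arrays. A stricter filter gave 900 lower. Without a minimum fold there were 2303 higher and 2644 lower, and at 4-fold 279 and 568. Leaving out 1 sample gave 1097 to 1419 higher and 1462 to 1763 lower.

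The count of probe sets that differ among lines was 794 in the 6 lines with 2 or 3 arrays, 1584 on numbered arrays only, 317 with the replicate number as a block, 330 without cRAF_cMYC and gammaA7, 249 without A2B1 replicate 1, and 83 to 788 with 1 array left out. In the 5 lines with 3 arrays, deviations of arrays from the mean of their line were correlated across lines: for unnumbered arrays 10 of 10 pairs lay over 0.1 (median 0.261). Of the replicate 1 pairs 6 of 10 and of the replicate 2 pairs 8 of 10 did, so the numbers were not used to pair arrays. The cause was not tested.

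With an estimated correlation the calls of mesenchymal (median 1.77), cell cycle (2.42), Myc target (1.72), antigen presentation (-2.91), immediate early (-1.64), type II (-4.74), club (-3.47), lymphocyte (-2.48) and endothelial (-2.95) lists were lost. With fry the Raf-MAPK (0.50), kinase inhibitor and tumour suppressor (0.44), xenobiotic (-2.32) and type I (-0.54) lists were called. The xenobiotic list was called after quantile normalization (-2.63), after centring (-1.79) and on numbered arrays only (-2.07), with a range of -2.99 to -1.97 over samples left out. The sterol list was called on numbered arrays only (0.82). The endothelial call was lost with an offset of 100 (-1.81), with a range of -3.64 to -1.93 over samples left out. Over samples left out the interferon median ran from -1.11 to -0.69, glycolysis from 0.0542 to 1.06 and immediate early genes from -2.17 to -0.99. The cause was not tested.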

Other observations

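No test in this part was chosen after the result was seen; the genes here were picked from the values and carry no new test.

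Line A2C12 held little RNA of Peg3 and Sgce, which are imprinted genes. The zinc finger gene Peg3 gave a signal of 28.7 in A2C12, below the 141 and 49.2 of the control arrays, and of 805 to 1846 in the other 10 lines (F-test adjusted p = 0.00171). Sgce gave 48.8 in A2C12 and 576 to 1775 in the other 10 lines (F-test adjusted p = 0.00246). Ndn, also imprinted, was low in A2C12 (8.48) but also in gammaA3 (8.19), gammaB8 (9.70) and betaD10 (18.2), and imprinted genes were not tested as a group. Of the 216 genes that differed among lines, A2C12 was lowest for 90 and highest for 76, and A2B1 was lowest for 28 and highest for 54.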
